A study of Mus musculus with 6 samples.

How the data were processed

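Polyadenylated RNA from whole mouse dorsal skin was sequenced in 6 libraries, 3 from DPCP with clodrosome and 3 from DPCP with encapsome, all at day 2. Per the labels' protocols, fresh skin was stabilised in RNAlater, RNA was isolated with TRIzol, and stranded mRNA libraries were sequenced as paired ends on a NovaSeq instrument. Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2 2.2.1, StringTie 2.2.1, featureCounts 1.6.2 and DESeq2 1.34.0, with the mm10 genome build. Per the file headers, the deposited values are raw read counts per gene made with featureCounts 1.6.2 on an Ensembl 102 annotation of GRCm38, the same assembly as mm10.

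The command in the file header sets no option for paired ends, strand, multiply mapped reads or reads that overlap several genes. With the defaults of that tool each read end is counted by itself, strand is ignored, and reads that map to several places or overlap several genes are left out. Of the counts from 1 to 20, between 63.6% and 69.7% per library were even, as when both ends of a fragment are counted. Counts are therefore about double the number of fragments, and an antisense gene cannot be told apart from its partner except where exons do not overlap. Genes with near-identical copies lose reads, and exons shared with another gene are blank. Itgam is affected, with 68.7% of its exonic bases covered by another gene's exons.

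The deposited table has 55487 genes and 6 count columns, with 0 further columns of sample values. The columns were matched to groups by name only, because the numbers in their names are not the replicate numbers of the sample titles. Libraries are called A, B and C within a group in column order. Symbols were found for 55227 of the gene identifiers (99.5%) in the GENCODE and name tables given for GRCm38, and coordinates are those of the deposited table. Where several identifiers share a symbol, a list uses the one with the most counts. The chi-square per gene between libraries of a group lay between 9.93 and 53.0, so no pair looked like a library deposited under 2 names. Sampling noise alone would give 1 for independent counts, and up to about 2 where both ends of each fragment are counted.

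Normalised values are CPM, counts scaled to a common library total, computed here from the deposited counts with TMM factors, which lay between 0.982 and 1.02. The upper limit that a count of 0 allows (3 fragments, taken as 6 counts because both ends can be counted; counting error only) was 0.0513 CPM in clodrosome library A and between 0.169 and 0.225 CPM in the others. The first principal component of log2 CPM (prior count 2) held 53.8% of the variance and separated the groups, with clodrosome libraries at -27.3, -44.9 and -33.7 and encapsome libraries at 38.4, 34.5 and 33.0. The next component held 14.5% and set clodrosome A, clodrosome C and encapsome A (13.7, 21.8 and 17.0) apart from clodrosome B, encapsome B and encapsome C (-28.3, -9.22 and -15.0). The share of counts in rRNA genes divided the libraries in the same way, at 0.355%, 0.334% and 0.481% against 0.796%, 0.845% and 0.788%, and the labels name no batch.

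Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, group as the only term) after filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over the 17988 genes kept, with a threshold of 0.05 and no fold minimum. The common biological coefficient of variation was 0.126. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. Positive values mean higher in clodrosome skin. Of the genes tested, 40.2% had groups that did not overlap, against 10% by chance for 3 against 3, and 6433 had an unadjusted p under 0.05.

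Before the data were examined, 40 gene lists were fixed, covering cell types of skin, hair follicle, keratinocyte states, signalling, inflammation and sample quality. Lists of at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 39 lists that qualified. The tested B and plasma cell genes were too few. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance to 1 side without reference to other genes, were alternatives. For each list the calls over all genes and those adjusted over the list alone were counted.

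The rule for naming genes was also fixed then. It takes 6 macrophage genes in every case, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, non-overlapping groups and a symbol that is not a clone name, and up to 4 members with the smallest p of each list described. Other genes are named as chosen after their values were seen. A gene that the rule selects from the macrophage list is not reported here.

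The procedure was tested on simulated counts with the means and library sizes of this comparison, over 17988 genes of which 200 were changed. It recovered 38.8% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 100% of those changed 4-fold, and 7 of its 148 calls were false. With no gene changed it made 0 calls. The changed genes had a mean of at least 1 CPM and random directions, and each gene was drawn independently. In the data 4035 genes were called, so the shares recovered and false may differ there.

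The settings varied, fixed at the same time, were median-ratio size factors, no low-count filter, leaving out each library, the Wald test of DESeq2 1.42.0, a minimum log2 fold change of 1, and the other list tests. Alternatives on FPKM or TPM values were not needed because the values used here are counts. After seeing the data, 5 were added: thinning the deepest library to 31566284 counts, halving the counts, offsets for GC content and gene length per library, scaling by library totals alone, and a term for the libraries with the higher rRNA share. Figures were drawn with matplotlib 3.10.9.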

Results

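The series measured polyadenylated RNA in whole dorsal skin of mice on day 2 of treatment with diphencyprone (DPCP), a contact sensitizer that provokes an allergic skin reaction. The skin of 3 libraries also received clodrosome, liposomes loaded with clodronate that kill the phagocytes which take them up. The skin of the other 3 libraries received encapsome, the matching liposomes without clodronate, and served as the control. The title of the series places the comparison in a study of macrophages in hair regrowth after contact hypersensitivity. The deposited table held read counts for 55487 mouse genes, with a total of 116965654 counts in clodrosome library A, 30605600 in B and 35566351 in C. The totals of encapsome libraries A, B and C were 31566284, 32066256 and 26649396 counts. The letters name table columns and do not pair libraries between groups. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these libraries.

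Clodrosome skin had lower levels of macrophage genes than encapsome skin at day 2. Adgre1, which encodes the macrophage surface marker F4/80, averaged 90.7 ± 25.7 CPM (SD, n = 3) with clodrosome and 242 ± 28.0 CPM (SD, n = 3) with encapsome. Mrc1, the mannose receptor of resident macrophages, averaged 260 ± 113 against 1021 ± 90.1 CPM, and Cd163, the haemoglobin scavenger receptor, 90.5 ± 56.7 against 416 ± 65.4 CPM (SD, n = 3 each). Over the whole transcriptome 4035 of 17988 tested genes differed between the groups at an edgeR adjusted p under 0.05, with 1692 higher and 2343 lower in clodrosome skin. Among genes with a fold difference of at least 2, lower genes outnumbered higher ones by 693 to 212. The counts depended on single libraries: 2477 genes were called without encapsome library B and 2642 without clodrosome library C, and the 1692 higher calls became 821, 933, 1122 and 938 without encapsome B, clodrosome C, encapsome A and encapsome C.

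The 6 macrophage genes chosen to check the depletion all fell. The log2 fold change of Adgre1 (chromosome 17, 57358691 to 57483527, GRCm38) was -1.41 ± 0.185 (SE; edgeR adjusted p = 8.58e-04), a 2.66-fold difference. Cd68, a lysosomal glycoprotein of phagocytes (chromosome 11, 69664213 to 69666153), fell by 2.01 ± 0.219 on the log2 scale (SE; edgeR adjusted p = 3.40e-04). Mrc1 (chromosome 2, 14229392 to 14332057) changed by -1.97 ± 0.293 (SE; edgeR adjusted p = 0.00166) and Cd163 (chromosome 6, 124304656 to 124330527) by -2.19 ± 0.468 (SE; edgeR adjusted p = 0.00967). C1qa, a chain of complement C1q made by macrophages (chromosome 4, 136895917 to 136898803), changed by -1.77 ± 0.306 (SE; edgeR adjusted p = 0.00355). Csf1r, the receptor for the macrophage growth factor CSF1 (chromosome 18, 61100598 to 61132149), changed by -0.94 ± 0.231 (SE; edgeR adjusted p = 0.0183), from 417 ± 72.9 to 217 ± 75.4 CPM (SD, n = 3 each). Every clodrosome library lay below every encapsome library for each of the 6 genes. The fall left a remainder, since Csf1r and Mrc1 still averaged 217 and 260 CPM with clodrosome. That remainder was uneven, and clodrosome library B was the lowest for each of the 6 genes. Cd163 stood at 25.4 CPM in B against 129 in A and 117 in C, and Mrc1 at 131 against 345 and 304. Adgre1 differed less, at 64.7 against 116 and 91.5 CPM. The call of Csf1r was lost without clodrosome library C (edgeR adjusted p = 0.0550) and without encapsome library A (edgeR adjusted p = 0.0625), and leaving out each library in turn gave adjusted p-values from 0.00477 to 0.0625.

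**Figure D1:**
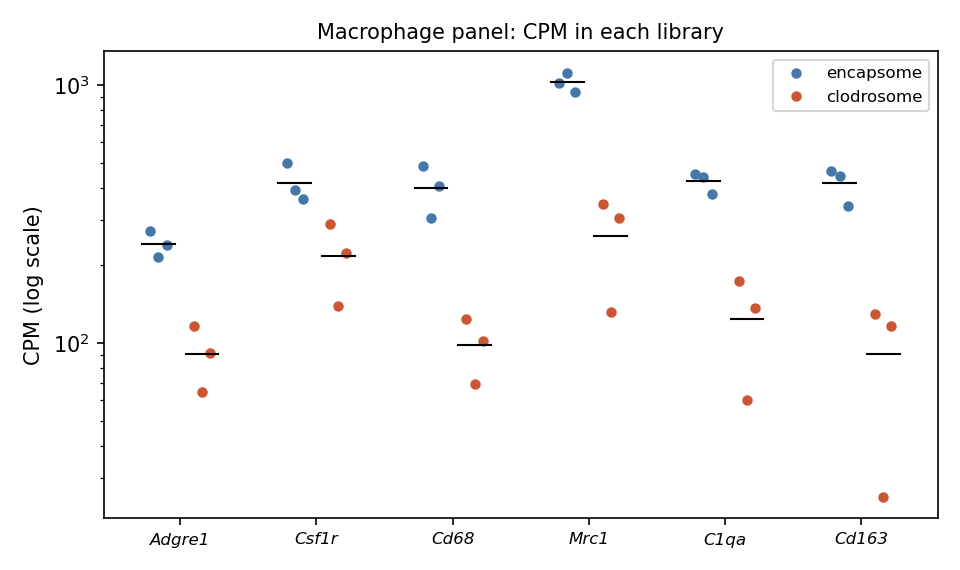
Normalised expression of the 6 macrophage genes in each library, in CPM on a log axis; points are single libraries (n = 3 per group) and black lines are group means. For each gene the 3 clodrosome libraries sit below the 3 encapsome libraries, as in Adgre1 with means of 90.7 and 242 CPM.

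The 10 largest falls lay between -6.04 and -3.21 on the log2 scale. Cd5l, a secreted protein of tissue macrophages, fell from 36.5 ± 16.7 to 0.612 ± 0.386 CPM (SD, n = 3 each), a log2 fold change of -6.04 ± 0.431 (SE; edgeR adjusted p = 8.25e-05). Atp6v0d2, a subunit of the vacuolar proton pump, changed by -5.44 ± 0.311 (SE; edgeR adjusted p = 4.42e-05). Gpnmb, a glycoprotein of lipid-laden macrophages and pigment cells, fell from 1212 ± 547 to 51.0 ± 14.2 CPM (SD, n = 3 each), a log2 fold change of -4.56 ± 0.367 (SE; edgeR adjusted p = 1.04e-04). Trem2, a lipid-sensing receptor of macrophages, changed by -3.25 ± 0.169 (SE; edgeR adjusted p = 4.42e-05) and Cd22, a sialic acid binding lectin best known from B cells, by -3.25 ± 0.356 (SE; edgeR adjusted p = 3.47e-04). The remaining members of this set were Stra6l at -4.40, Serpina3b at -4.03, the neuropeptide gene Npy at -3.52, Tm4sf19 at -3.42 and the axon guidance gene Draxin at -3.21, with edgeR adjusted p-values from 8.25e-05 to 0.00417. With clodrosome Npy and Serpina3b averaged only 0.247 and 0.300 CPM, so the sizes of their falls rest on few counts. Serpina3b also belongs to a family of near-identical genes, and its count is uncertain because reads that matched several places were left out.

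The 10 largest rises were smaller, between 1.83 and 2.62 on the log2 scale. Ubd, a ubiquitin-like protein induced by cytokines, rose from 3.60 ± 0.314 to 22.1 ± 8.45 CPM (SD, n = 3 each), a log2 fold change of 2.62 ± 0.279 (SE; edgeR adjusted p = 3.04e-04). Selp, the adhesion molecule P-selectin of venules and platelets, rose from 21.0 ± 5.90 to 124 ± 28.4 CPM (SD, n = 3 each), a log2 fold change of 2.56 ± 0.223 (SE; edgeR adjusted p = 1.33e-04). Car4, a membrane-bound carbonic anhydrase, rose from 30.4 ± 7.07 to 124 ± 6.23 CPM (SD, n = 3 each; log2 fold change 2.02; edgeR adjusted p = 8.51e-05). The neutrophil gene Retnlg rose by 2.07 ± 0.230 (SE; edgeR adjusted p = 3.66e-04). The muscle genes Actc1, cardiac alpha-actin, and Tnnc1, slow muscle troponin C, rose by 2.56 and 2.04, with edgeR adjusted p-values of 0.00516 and 0.0120. The remaining rises were Prl2c5 at 2.16, Gimap3 at 1.93, Gbp10 at 1.89 and the cation channel gene Trpc6 at 1.83, with edgeR adjusted p-values from 8.39e-04 to 0.00644. Prl2c5 and Gbp10 have close paralogs and are uncertain for the same reason as Serpina3b, and exons of another gene on the same strand cover 46.3% of the exonic bases of Gbp10. With encapsome Prl2c5, Tnnc1 and Trpc6 averaged only 0.448, 0.468 and 0.706 CPM, so the sizes of their rises rest on few counts.

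**Figure D2:**
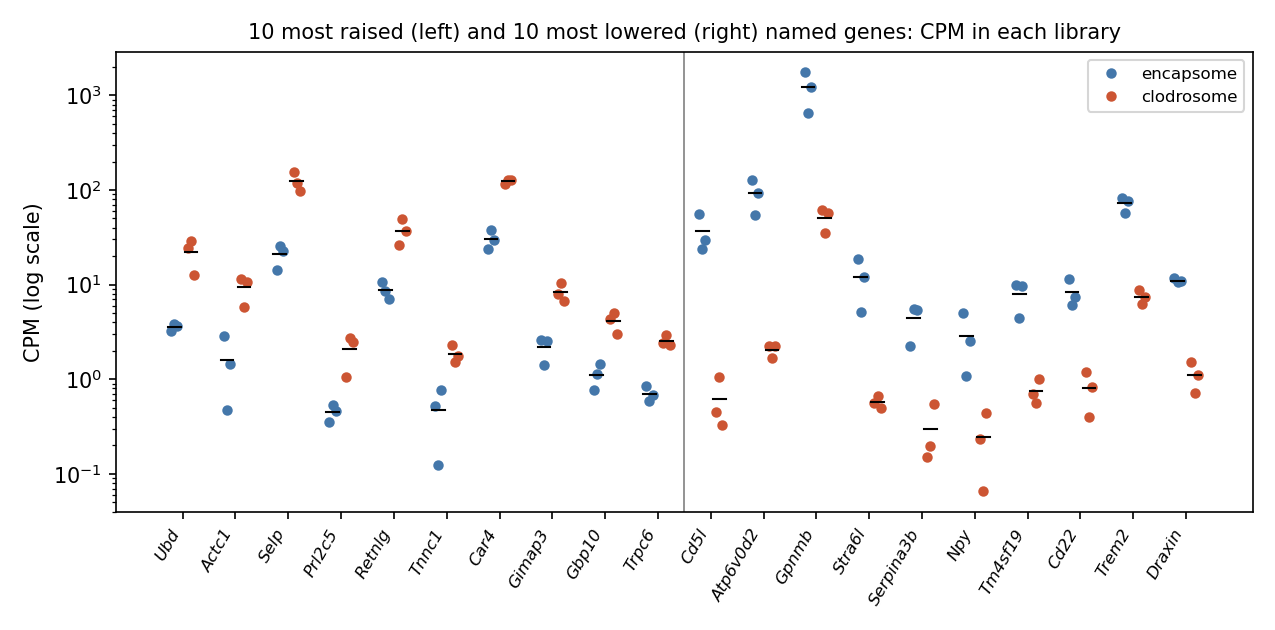
Normalised expression of the 10 named genes with the largest rises (left) and the 10 with the largest falls (right), in CPM on a log axis; points are single libraries (n = 3 per group) and black lines are group means. In the extremes, Ubd averaged 3.60 CPM with encapsome and 22.1 CPM with clodrosome, and Cd5l averaged 36.5 and 0.612 CPM.

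Gene lists fixed in advance were tested with camera, which compares a list with all other tested genes. Of 39 tested lists 16 differed at an adjusted p under 0.05, of which 8 were lower and 8 higher in clodrosome skin. Some lists share members, so the 16 results are not independent. Fcgr3 and Fcgr1 are in the macrophage and the complement and Fc receptor lists, and Col1a1 is in the fibroblast and the collagen lists. With a correlation between genes estimated from the 6 libraries, camera called 0 of the 39 lists, 5 of them had an unadjusted p under 0.05, and the test fry called 15. Among the called lists the estimate ran from -0.033 to 0.624, against the preset 0.01, so very small camera p-values below lean on the preset.

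Of the 30 macrophage genes tested, 27 fell, with a median log2 fold change of -1.66 (camera adjusted p = 9.85e-24; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 1.95e-48). Adjusted over the list alone, 27 were lower and 2 higher. The Fc receptors Fcgr3 and Fcgr1 changed by -1.65 and -1.35. Cd14, a co-receptor for lipopolysaccharide picked out after its value was seen, rose by 0.52, a call lost without each clodrosome library in turn (edgeR adjusted p from 0.0532 to 0.0647). Genes of complement and Fc receptors were lower in 14 of 20 cases, with a median of -1.14 (camera adjusted p = 2.46e-13; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 4.23e-26), or 15 lower and 1 higher adjusted over the list alone. Fcer1g, the shared signalling chain of Fc receptors, changed by -1.20, and C3ar1, the receptor for complement C3a, by -1.58. The MHC class II list, which presents antigen to helper T cells, had 7 of 10 members lower both over all genes and adjusted over the list alone, with a median of -1.03 (camera adjusted p = 7.86e-11; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 3.05e-19). Its members H2-Aa and H2-Eb1 changed by -1.02 and -1.04.

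The list of macrophage activation genes was lower by camera (adjusted p = 0.00504; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 1.27e-05), with 8 of 20 genes lower and a median of only -0.08, which was -0.05, -0.16, -0.18 and -0.06 without clodrosome A, clodrosome C, encapsome A and encapsome C. Adjusted over the list alone, 9 were lower and 2 higher. Its lower members included Trem2, Gpnmb and Mmp12, an elastase of macrophages, at -1.83. The prostaglandin synthase gene Ptgs2 and the cytokine gene Tnf, named after their values were seen, rose by 0.87 and 0.79, and the call of Tnf was lost without clodrosome library A, encapsome library A or encapsome library B (edgeR adjusted p = 0.0576, 0.0666 and 0.0837). The lists of monocyte genes (median -0.33, camera adjusted p = 0.170) and of dendritic and Langerhans cell genes (median -0.11, camera adjusted p = 0.0869) did not pass. The monocyte list did without encapsome library A (camera adjusted p = 0.0142) and with no low-count filter (camera adjusted p = 0.0309), over a range from 0.0142 to 0.738, and its median was -0.21 without clodrosome library C. The dendritic list did with no low-count filter (camera adjusted p = 0.0133) and by fry (adjusted p = 0.0356), over a range from 0.0133 to 0.502, and its median was -0.25, -0.21 and -0.07 without clodrosome B, encapsome B and clodrosome A. Among 12 monocyte genes 5 were lower and 1 higher, with Fcgr4 and Ccr2 at -1.44 and -0.78 and Clec4e at 0.97. Among 17 dendritic and Langerhans cell genes 5 were lower and 3 higher. There the integrin gene Itgax fell by 0.95 and the lectin gene Cd209a by 1.63 on the log2 scale. Ccr7, the homing receptor of migrating dendritic cells, named after its value was seen, rose by 1.07 (edgeR adjusted p = 0.00135).

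Fibroblast and matrix genes were also lower in clodrosome skin. Of 14 fibroblast genes 10 fell, with a median log2 fold change of -1.10 (camera adjusted p = 1.59e-10; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 2.67e-20), or 12 adjusted over the list alone. Col1a1 and Col1a2, the chains of type I collagen, changed by -1.90 ± 0.174 (SE) and -1.61 ± 0.183 (SE), with edgeR adjusted p-values of 1.63e-04 and 4.16e-04, and Lum, the collagen-binding lumican, by -1.76. Fbln1, Postn, Dpp4 and Pi16, named after their values were seen, did not pass, although Fbln1 did without clodrosome library A (edgeR adjusted p = 0.0149). Of 27 genes of collagen and matrix remodelling 19 fell and 3 rose, with a median of -0.79 (camera adjusted p = 2.93e-10; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 1.33e-19), or 20 lower and 4 higher adjusted over the list alone. Tnc, the wound matrix protein tenascin C, changed by -2.74, and the matrix protease gene Mmp14 by -1.03. The rises were in Timp3, Mmp10 and Col7a1, at 0.61, 0.93 and 0.49, named after their values were seen. The call of Col7a1 was lost without clodrosome library A or C and without encapsome library A or C (edgeR adjusted p from 0.0545 to 0.0683).

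The basal and differentiated keratinocyte lists moved in opposite directions, although members of the differentiated list went both ways. RNA of whole skin cannot tell a change within these cells from a change in their share of the tissue. Of 10 basal keratinocyte genes 7 rose, with a median of 0.45 (camera adjusted p = 8.13e-05; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 3.82e-07), or 8 adjusted over the list alone. Trp63, a transcription factor of epidermal progenitors, rose by 0.53, Krt5, a basal keratin, by 0.66, and the laminin gene Lamb3 by 0.51. Of 17 genes of differentiated keratinocytes 9 fell and 2 rose, with a median of -0.69 (camera adjusted p = 0.0311; adjusted p = 0.626 with an estimated correlation, the highest over all alternatives, the lowest being 1.37e-04), or 9 lower and 3 higher adjusted over the list alone. Lor, a protein of the cornified envelope, changed by -2.18 and Krt10, a keratin of the layers above the basal one, by -1.36, while Cnfn and Sbsn, named after its value was seen, rose by 0.46 each. The call of Sbsn was lost without encapsome library B or C (edgeR adjusted p = 0.0519 and 0.0526). The call of the differentiated list was lost without clodrosome library A (camera adjusted p = 0.0802) and without encapsome library A (camera adjusted p = 0.0953, with the median at -0.41), and leaving out each library in turn gave adjusted p-values from 2.12e-04 to 0.0953. Activated keratinocyte genes did not pass as a list (median 0.16, and 0.30, 0.27 and 0.10 without clodrosome C, encapsome A and encapsome C; camera adjusted p = 0.0852; 0.0404 and 0.00872 without clodrosome library B and encapsome library A, 0.0468 with no low-count filter, and up to 0.626 over all alternatives), although the wound keratin Krt17 rose by 0.65 and Sprr1b by 0.72. Cell cycle genes rose in 18 of 34 cases, with a median of 0.25 (camera adjusted p = 1.36e-06; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 2.75e-09), or 21 higher and 1 lower adjusted over the list alone. The replication helicase gene Mcm7 rose by 0.57 and Ccne1, cyclin E1, by 0.47.

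Hair follicle stem cell genes were higher as a list, with 5 of 15 higher and 2 lower and a median of 0.23 (camera adjusted p = 0.0211; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 0.002), or 7 higher and 2 lower adjusted over the list alone. The transcription factor genes Lhx2, Barx2, Sox9 and Tbx1 rose by 1.14, 1.23, 0.71 and 0.98, and the matrix gene Npnt by 0.50, the latter pair named after their values were seen. Aldh1a2, an enzyme that makes retinoic acid and the list member with the smallest p, fell by 3.07 on the log2 scale (edgeR adjusted p = 5.99e-05). Tcf7l1, named after its value was seen, changed by -0.39, a call lost without any 1 of the 6 libraries (edgeR adjusted p from 0.0596 to 0.131). The hair growth factor list did not pass (median 0.17, mean -0.02, camera adjusted p = 0.948), but single members fell. Hgf, hepatocyte growth factor, changed by -2.17 ± 0.176 (SE; edgeR adjusted p = 1.06e-04), Igf1 by -1.31 ± 0.153 (SE; edgeR adjusted p = 4.85e-04) and Fgf7, keratinocyte growth factor, by -1.45 ± 0.236 (SE; edgeR adjusted p = 0.00264), while Osm, oncostatin M, rose by 0.55. The dermal papilla list (median -0.37, camera adjusted p = 0.0654; 0.0441, 0.0158, 0.0241 and 0.0471 without clodrosome A, clodrosome C, encapsome A and encapsome C) did not pass over all libraries, but did with no low-count filter (camera adjusted p = 0.00361) and by fry (adjusted p = 0.0499), over a range from 0.00361 to 0.502. The Wnt pathway list (camera adjusted p = 0.610, with a median and a mean of opposite sign) did not pass either. In the dermal papilla list Crabp1, a retinoic acid binding protein, changed by -2.29, and in the Wnt list the secreted modulators Sfrp1 and Dkk2 by 0.83 and -1.04. Of 37 listed hair shaft and inner root sheath genes, 12 had enough counts for a test and the list did not pass (camera adjusted p = 0.402).

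Among other immune cells, neutrophil genes were higher and mast cell genes lower. Of 18 neutrophil genes 7 rose, with a median of 0.46 (camera adjusted p = 8.67e-06; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 1.18e-09), or 8 adjusted over the list alone. Lcn2, the iron-binding lipocalin of neutrophils and inflamed epidermis, rose by 1.72, Acod1, which makes itaconate, by 1.37 and Hcar2, a metabolite receptor, by 0.91. Of 12 mast cell genes 7 fell, with a median of -0.88 (camera adjusted p = 3.88e-04; adjusted p = 0.502 with an estimated correlation, the highest over all alternatives, the lowest being 6.44e-07), or 9 lower and 1 higher adjusted over the list alone. The proteases Cpa3 and Cma1 changed by -0.95 and -0.84. Hdc, the histamine-forming enzyme, named after its value was seen, rose by 0.96. The T and NK cell list did not pass (median 0.32, and 0.17 and 0.19 without clodrosome library B and encapsome library B; camera adjusted p = 0.375), nor did the interferon response list (median -0.19, camera adjusted p = 0.191; 0.0448 without encapsome library A, 0.0390 with no low-count filter, and up to 0.626 over all alternatives).

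Chemokine genes went both ways, with 8 of 29 higher and 8 lower (camera adjusted p = 0.402; 9 higher and 8 lower adjusted over the list alone). The macrophage-derived chemokine genes Ccl6, Ccl9 and Ccl12 changed by -1.65, -1.20 and -1.63, while the T cell attractant Ccl5 rose by 1.69. The cytokine list did not pass (camera adjusted p = 0.826). Csf3, the growth factor of neutrophils, rose by 1.74 (edgeR adjusted p = 0.00342) and Il23a, a subunit of interleukin 23, by 1.33. Il24 and Tnfsf11, the osteoclast factor RANKL, changed by -0.81 and -1.63.

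Blood vessel, muscle and stress genes moved together with the groups. Of 11 blood endothelium genes 6 rose, with a median of 0.42 (camera adjusted p = 2.80e-04; adjusted p = 0.36 with an estimated correlation, the highest over all alternatives, the lowest being 3.05e-06), or 7 adjusted over the list alone. The endothelial genes Pecam1, Egfl7 and Kdr rose by 0.59, 0.47 and 0.46. Of 13 skeletal muscle genes 7 rose, with a median of 0.57 (camera adjusted p = 8.13e-05; adjusted p = 0.0782 by fry; adjusted p = 0.502 with an estimated correlation, the highest over all alternatives, the lowest being 7.83e-08), or 9 adjusted over the list alone. Skeletal alpha-actin, Acta1, rose by 0.60 and the myosin heavy chain gene Myh2 by 1.05. Of 19 genes of dissociation and immediate early stress 6 rose, with a median of 0.34 (camera adjusted p = 0.00162; adjusted p = 0.326 with an estimated correlation, the highest over all alternatives, the lowest being 4.20e-05), or 7 adjusted over the list alone, with Ier3 at 0.68 and Egr2 at 0.34. Genes of fatty acid and cholesterol synthesis rose in 9 of 20 cases and fell in 3, with a median of 0.26 (camera adjusted p = 0.0335; adjusted p = 0.502 with an estimated correlation, the highest over all alternatives, the lowest being 0.00471), or 11 higher and 3 lower adjusted over the list alone. The sterol enzymes Cyp51, Lss and Sqle rose by 0.42, 0.64 and 0.40 and the fatty acid desaturase Scd1 changed by -0.89. That list's call was lost without clodrosome library A, encapsome library B or encapsome library C (camera adjusted p = 0.0525, 0.0690 and 0.168), and leaving out each library in turn gave values from 0.00471 to 0.168. The lower values of red blood cell genes did not pass as a list (median -1.21, camera adjusted p = 0.0502). They did so without clodrosome library C and without encapsome libraries A, B and C (camera adjusted p = 0.00768, 3.47e-04, 0.0473 and 0.00351), and over all alternatives the value ran from 3.47e-04 to 0.626. Without encapsome library B the median was -0.56.

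**Figure D3:**
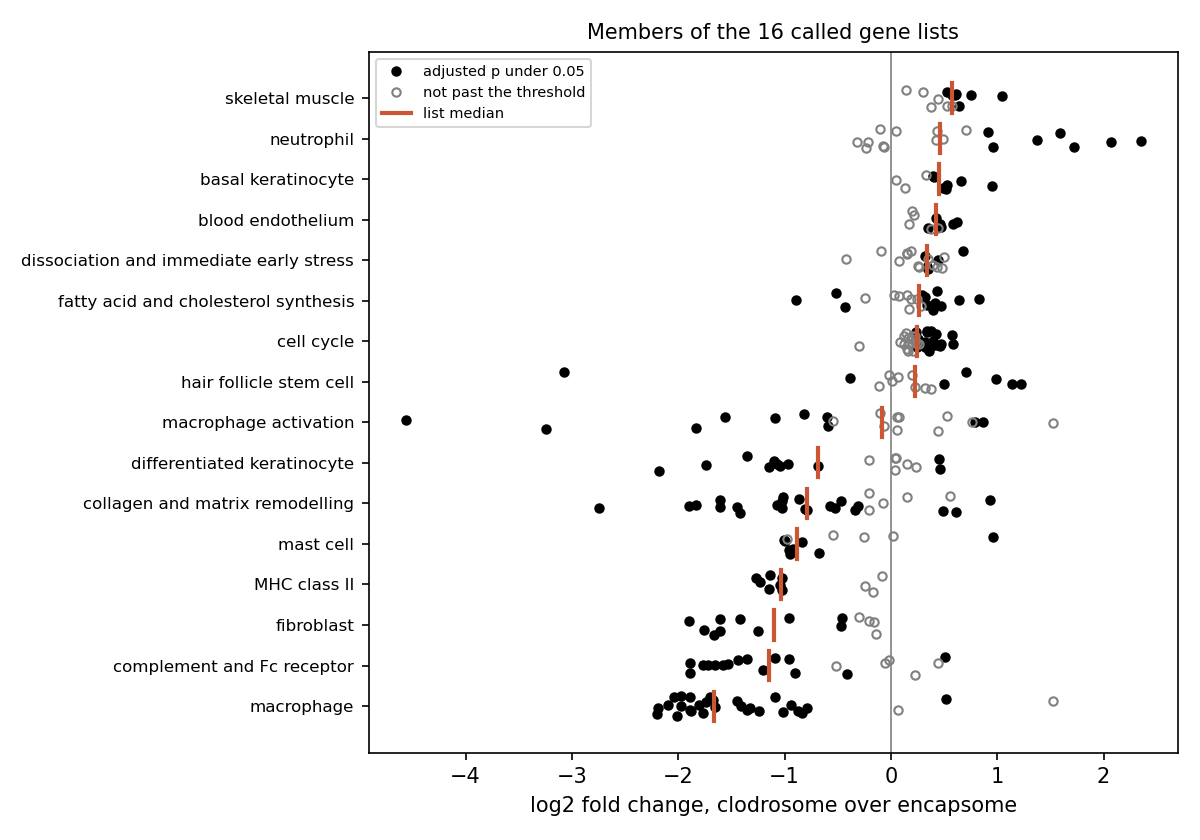
Log2 fold changes (clodrosome over encapsome) of the tested members of the 16 lists called by camera, 1 line per list; filled points passed an edgeR adjusted p of 0.05, open points did not, and bars are list medians. The medians run from -1.66 for macrophage genes to 0.57 for skeletal muscle genes.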

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

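The alternatives that thin the deepest library, halve the counts, correct for GC content and length, scale by library totals alone, or add a term for rRNA share were chosen after seeing the data, as were the tests of the later lists; the others were planned. Of the 236 genes, 39 lists and 5 later lists followed here, 0 changed direction with a call by edgeR, DESeq2, camera or fry under the alternatives that gave them a value. Requiring a log2 fold change of at least 1 left 905 genes called (212 higher and 693 lower), by construction fewer than 4035. Leaving out each library in turn gave 2477 to 4396 called genes, 821 to 1964 higher and 1656 to 2432 lower, with fewer libraries in each fit. Of the 4035 genes, 2389 were called in the same direction without encapsome library B, 2550 without clodrosome library C and 2982 without clodrosome library A. The other alternatives stayed within 1.5 times the count, between 3934 (deepest library thinned) and 4729 (no low-count filter), and shared 3676 to 3998 of the calls in the same direction. A term for the 3 libraries with the higher rRNA share, 2 of them encapsome, gave 4276 genes (1780 higher, 2496 lower), 3676 of them shared, and ended the call of fatty acid and cholesterol synthesis (camera adjusted p = 0.0681). Scaling by library totals alone moved the share of higher calls from 41.9% to 49.7% and the median log2 fold change of all genes from 0.01 to 0.04.

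Camera called 16 lists, and with an estimated correlation 0 (5 at an unadjusted p under 0.05). Estimates for the called lists ran from -0.033 (hair follicle stem cell) to 0.624 (MHC class II), against the preset 0.01. The macrophage and fibroblast lists had 0.53 and 0.57, so their small camera p-values rest on a near-independence of genes that these libraries do not show. The hair follicle stem cell and macrophage activation lists, at -0.033 and -0.031, lost the call too, and the cause there was not tested. Fry called 15 and lost 3 of the lists called by camera, skeletal muscle (adjusted p = 0.0782), differentiated keratinocyte (0.129) and fatty acid and cholesterol synthesis (0.0588); leaving out each library gave 15 to 20, and no low-count filter gave 23, where 7 lists gained a call and 0 lost it (monocyte, dendritic, adipocyte, activated keratinocyte, dermal papilla, interferon response and red blood cell). Of the 5 later lists 4 lost their call with an estimated correlation, and the GTPase list alone also lost it by fry and without clodrosome or encapsome library A. No paired analysis was possible because the columns carry no replicate number of the sample titles. A limma fit on FPKM or TPM and the smaller pseudocount were not run, since counts were used. Of the 236 genes, 4 lost and 0 gained a call with the deepest library thinned, and 34 lost and 1 gained it without encapsome library B, the largest loss among the alternatives. Depth limits low genes: a count of 0 allows up to 0.225 CPM in the shallowest library, with 3 fragments taken as 6 counts.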

Other observations

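The gene lists of this part were chosen after the results had been seen, and so were the tests of dermis share, matched genes, muscle, vessels, lymph node and platelets; the tests of offsets for GC content and length, of the deep library and of other splits of the libraries were chosen before their results. Lysosome and lipid handling genes, many of them highly expressed in phagocytes, fell in 28 of 34 cases with a median log2 fold change of -0.87 (camera adjusted p = 5.49e-37; adjusted p = 0.0606 with an estimated correlation). Without Trem2, Atp6v0d2 and Gpnmb, which led to the list, 25 of 31 were lower with a median of -0.82 (camera adjusted p = 2.66e-27; adjusted p = 0.0795 with an estimated correlation). Ctss, a cysteine protease of antigen-presenting cells, went from 1754 ± 271 to 386 ± 40.5 CPM (SD, n = 3 each; edgeR adjusted p = 4.42e-05). Lipa, the acid lipase that frees cholesterol in lysosomes, changed by -2.08, Psap, the precursor of the saposins, by -1.72 and Grn, progranulin, by -1.55. Ctsl and Fabp5, which keratinocytes also express, did not pass.

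Of 20 interferon-inducible GTPase genes 7 were higher and 2 lower, with a median of 0.19 (camera adjusted p = 0.0187; adjusted p = 0.587 with an estimated correlation, 0.255 by fry). The call was lost without Gbp10, which led to the list (camera adjusted p = 0.0581), without clodrosome library A (camera adjusted p = 0.185, median 0.06) and without encapsome library A (camera adjusted p = 0.144, median 0.07), and without clodrosome library C and encapsome library C the median was 0.30 and 0.29. Gbp11 rose by 1.75 and Gbp8 changed by -1.14, both uncertain because the family has near-identical copies.

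The split of the libraries by treatment called 4035 genes with edgeR, and the highest of the other 9 splits of the 6 libraries into 3 and 3 called 0, with 1117 genes at an unadjusted p under 0.05 in the split with most, that of clodrosome A, clodrosome C and encapsome A against the rest, which the rRNA share follows too. Only 1 of the 10 splits reached the count, and 10 splits are too few for a share under 0.05.

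The lower fibroblast and matrix genes form the first pattern, with a median log2 fold change of -0.79 over the 35 genes of both lists (quartiles -1.33 and -0.20). Offsets for GC content and length left the median at -0.77 but moved fold changes by a median of only 0.0134; more directly, the 50 genes outside the lists closest to each member in GC content and length had medians from -0.11 to 0.13, with a middle value of -0.00805. Leaving out clodrosome library A, sequenced 3.71 times as deeply as the median of the others, left the median at -0.76, so neither that depth nor GC content and length account for the whole fall. A smaller share of dermis in the clodrosome pieces cannot be told apart from a treatment effect, because lists of the dermis went both ways. The blood endothelium list had a median of 0.42. The lymphatic endothelium, nerve and Schwann cell, and smooth muscle and pericyte lists, which did not pass, had medians of 0.45, 0.39 and 0.17. The mast cell list had a median of -0.88 and the dermal papilla list, which did not pass over all libraries, -0.37. More muscle could also bring vessels. Less dermis would raise the share of epithelial genes, and these lists went both ways too. The basal keratinocyte and hair follicle stem cell lists had medians of 0.45 and 0.23, and the differentiated keratinocyte list -0.69. The small rises of the epithelial lists therefore cannot be told apart from a change in tissue share either. An effect of the clodrosome treatment on fibroblasts, direct or through lost macrophages, also stays open and was not tested.

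Muscle genes form the second pattern. All 13 tested mature skeletal muscle genes had positive log2 fold changes and none was called lower. These values restate the rise of that list, so they cannot tell more muscle in the clodrosome pieces from a treatment effect on muscle. Of the muscle differentiation genes 9 of 16 were higher, with a median of 1.43 (camera adjusted p = 4.31e-08, and 0.160 with an estimated correlation). Without Actc1, Tnnc1, Myog and Mymk, which prompted the list, 5 of 12 were higher with a median of 1.17 (camera adjusted p = 1.89e-05, and 0.165 with an estimated correlation). Myog, a transcription factor of muscle differentiation, rose by 1.70, and the acetylcholine receptor gene Chrna1, which did not prompt the list, by 1.34. Within libraries the log2 ratio of differentiation to mature genes was 0.87 higher with clodrosome (-6.63 ± 0.364 against -7.50 ± 0.626, SD, n = 3 each). Encapsome library B had the lowest ratio, -8.19, and clodrosome C and encapsome A almost met, at -6.963 and -6.975. Without the 4 genes that prompted the list the difference was 0.60 and the groups overlapped. An exact test of 3 against 3 cannot go below p = 0.1. Uneven sampling of muscle and a treatment effect on muscle therefore cannot be told apart for the differentiation genes, because the ratio separates the groups only through those genes.

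Endothelial adhesion and venule genes form the third pattern, with 6 of 8 higher and a median of 1.87 (camera adjusted p = 3.17e-08, and 0.0606 with an estimated correlation). Without Selp, which prompted the list, 5 of 7 were higher with a median of 1.18 (camera adjusted p = 1.14e-05, and 0.0795 with an estimated correlation). Besides Selp, E-selectin Sele rose by 1.18 and the chemokine-binding Ackr1 by 0.69. Madcam1, Glycam1 and Chst4, known from lymph node venules, rose from means of 0.116, 0.127 and 0.151 CPM to 1.03, 1.10 and 1.02 CPM. The adhesion genes Icam1 and Vcam1 did not pass, at 0.26 and 0.10 (edgeR adjusted p = 0.176 and 0.669), although Icam1 did without clodrosome library B (edgeR adjusted p = 0.0443). The log2 ratio of the adhesion and venule list to the endothelium list within libraries was 1.30 higher with clodrosome (-2.03 ± 0.132 against -3.33 ± 0.387, SD, n = 3 each). It was 1.17 higher without Selp and 0.57 higher over members of at least 1 CPM, each without overlap of the groups. With both choices the difference was 0.16 and the groups overlapped. More vessels and a change in the vessels therefore cannot be told apart, because separation without Selp rests on Madcam1, Glycam1 and Chst4, with encapsome means below the limit that a count of 0 allows. Lymph node tissue cannot be told apart either. The tested B and plasma cell genes had a median of -0.71, with 2 of 3 called lower and 0 higher. Ighm and Cd79b changed by -0.71 and -1.43 (edgeR adjusted p = 0.00588 and 0.0144), and the call of Cd79b was lost without encapsome library A or B. Where more genes entered, the sign varied. The median was 0.58 over 10 genes with no low-count filter. Without each library it lay between -0.32 and 0.89 over 4 to 6 genes. Platelets as a source of Selp would bring their own genes, whose median was -0.0766 over 6 genes, and from -0.27 to 0.07 over the alternatives; a treatment effect on endothelium stays open and was not tested.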
